A study of Saccharomyces cerevisiae with 3 samples.

How the data were processed

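The series measured total RNA of Saccharomyces cerevisiae on 3 arrays. Per the labels' protocols, the yeast was a W303 MAT-alpha strain with the cdc15-2 mutation, a temperature-sensitive allele of a kinase needed to leave mitosis, sampled 340 minutes after release from the restrictive temperature into growth at 23 °C. Double-stranded cDNA was transcribed in vitro into biotin-labelled RNA, per the labels' protocols. The arrays held the yeast background alone (100% baseline), 99% baseline with 1% spike and 90% baseline with 10% spike. The labels used here do not say what the spike was or which probe sets it targets. Each group is 1 array, so no difference has a replicate check. No significance test between arrays was run, no p-value is given, and the number of arrays limits the precision of every value.

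The deposited values are log2 expression values, 1 per probe set and array, and the submitters' processing notes name RMA (robust multi-array average, which corrects background, equalizes the distributions of the arrays and summarizes the probes of a probe set by median polish). That the scale is log2 rests on RMA's usual output and on the range of the values, 3.47 to 15.13; no label states it. The sorted values of the 3 arrays lay within 0.051 (1% array) and 0.092 (10% array) of those of the baseline array. Which arrays were normalized together, the RMA version and the scanner settings are not given in the sources used here. The values were used as deposited. Such processing can hide a shift common to most of the RNA, because the arrays are given nearly the same distribution. With 3 arrays, median polish can also return exactly equal values.

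The table had 10928 probe sets. Of these, 166 had an ID starting with AFFX and were treated as the array maker's controls, outside all counts, and 10762 remained. Names came from a platform annotation, and symbols were updated through gene identifiers to a table of S. cerevisiae assembly R64, which changed 12 symbols. In all, 7244 probe sets had 1 symbol, 1 had several and 3683 had none. The symbols of 5498 probe sets were S. cerevisiae genes (5449 distinct genes). Those of 1747 were not in the S. cerevisiae table; they begin in lower case, and the sources used here do not give their organism. Besides these, 3470 probe sets were unnamed here and 47 were reporter sequences. Some control IDs are marked Sp and others Sc, so the array may also carry probe sets for another organism. Probe sets with other symbols or without a name may therefore not target the yeast used here. No coordinates are given, because the sources name no genome build for the probes.

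Differences of log2 values were taken for 1% over baseline, 10% over baseline and 10% over 1%, and rounded to 3 decimals. Probe sets at or past 1 or -1 (2-fold) were counted. Linear increments are 2 to the power of the spiked array's value minus the same for the baseline array. For 23 gene lists fixed before the data were examined, the median difference of each list was placed among 10000 random lists of the same size drawn from the named S. cerevisiae genes and matched on mean level in 20 bins. Probe sets of a gene were averaged there. Percentiles under 2.5 or over 97.5 were called apart from random lists; they describe these arrays only. The genes named in the text follow a rule set before the data were examined. For each comparison it takes the 10 largest rises and falls at or past 2-fold whose mean level was above the lower quartile, and for the set higher in both spiked arrays those with the largest rises and the extremes of the 10% over 1% difference. In each list it takes up to 4 members with the largest absolute difference (taken in 10% over baseline) and the 2 nearest the list's median. CDC15 and the mating-type and marker genes MATALPHA1, MATALPHA2, ADE2, URA3, HIS3, LEU2, TRP1 and CAN1 were added by name. The lists cover cytosolic ribosomal proteins, ribosome biogenesis, glycolysis and fermentation, oxidative phosphorylation with the TCA cycle, the general stress response, heat shock chaperones, the proteasome, amino acid biosynthesis, ergosterol biosynthesis, the iron and phosphate regulons, G1/S genes, core histones, the CLB2 cluster, M/G1 genes, alpha-specific, a-specific and haploid genes, meiosis, telomeric families, hexose transporters, galactose genes and mitochondrially encoded genes.

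The counting and list steps were tested on simulated data made from the 10762 probe sets for the 10% over baseline comparison, with 200 probe sets changed. The count took up 0% of the 1.5-fold, 90% of the 2.2-fold, 100% of the 4-fold and 100% of the 8-fold changes. It took up 0% of the unchanged probe sets, whose noise came only from probe sets under 2-fold in every comparison. That 0% was therefore fixed in advance and does not show how specific the count is. By their medians among 10000 random lists, lists of 30 raised by 0.1 (log2) were called apart in 100% of 40 cases and unchanged lists in 2.5%. The largest list median found was 0.028 in size, so this does not show how often shifts that small would be called. Alternatives were thresholds of 1.5-fold and 4-fold, leaving out dim probe sets (mean level in the lower quartile), centring each array on its median, quantile normalization over again, removal of a loess trend on level, averaging probe sets per named gene, keeping controls, leaving out the spike-responding probe sets and unmatched random lists, drawn with replacement. An alternative was read as leaving a count as it was when within 1.5 times, a correlation when within 0.01, and another value when it moved by less than 0.5 of the 95% range of all probe sets' differences; these limits were chosen after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 were used.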

Results

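Gene expression was measured on 3 yeast arrays with Affymetrix probe sets, 1 each for the yeast background alone, the background with 1% spike and the background with 10% spike. The series title and design frame the question as how a yeast background behaves when material is spiked in at high concentration. The median log2 value over the 10762 non-control probe sets was 7.75 in the baseline array, 7.77 in the 1% array and 7.73 in the 10% array. There were no replicates, so sizes are given without an error. Each size can be set beside the spread of all probe sets, of which 95% lay between -0.12 and 0.13 for 1% over baseline and between -0.23 and 0.26 for 10% over baseline. That spread is a rough guide, since it differs by class and level. In 10% over baseline, 95.6% of S. cerevisiae probe sets (median level 10.82) lay within 0.2, against 88.8% of unnamed ones (median level 4.95).

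Adding 1% spike was accompanied by large increases at very few probe sets. Of the 10762 probe sets, 7 were at least 2-fold higher than in the baseline array and 0 were at least 2-fold lower. None of the 7 carries a gene name in the annotation used here. The probe set 1773133_at went from 4.67 to 14.37, a measured difference of 9.70, and 1774104_s_at went from 5.46 to 14.71, one of 9.25. The probe set 1769984_at went from 6.85 to 12.66, one of 5.81. The other 4 had smaller differences. The probe set 1774972_at was higher by 2.08, 1778502_at by 1.86, 1773248_at by 1.33 and 1769739_at by 1.29. The baseline values of these 7, and of the further probe sets at least 2-fold higher in the 10% array, all lay below the baseline array's median of 7.75. Low values can hold mostly background signal, so the increases of these probe sets over the baseline array are read as lower bounds and not given as folds. None of the 5498 S. cerevisiae probe sets reached 2-fold in either direction, and their differences ran from -0.58 to 0.24. At 1.5-fold their count was also 0 in both directions.

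**Figure D1:**
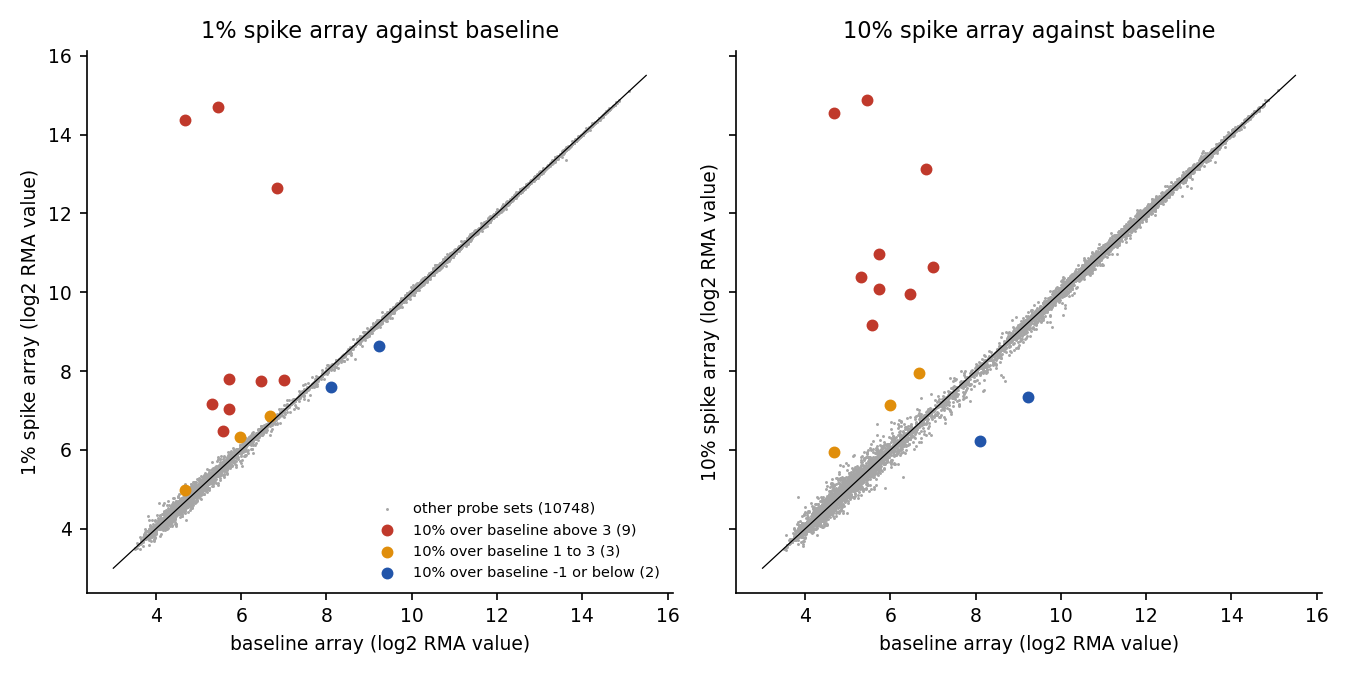
Log2 RMA value of each non-control probe set in the 1% spike array (left) and the 10% spike array (right) against the baseline array, 1 array each, with the line of equal values. The 9 probe sets drawn in red lie more than 3 (log2) above the line at 10% spike, 3 in orange lie 1 to 3 above it, and 2 in blue lie more than 1 below it.

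In the 10% array, 12 probe sets were at least 2-fold higher than in the baseline array and 2 were at least 2-fold lower. The 9 largest increases were separated from the rest by a gap, since the smallest of them was 3.50 and the next probe set was at 1.28. The 3 bright probe sets remained the largest, with differences of 9.89 for 1773133_at, 9.42 for 1774104_s_at and 6.28 for 1769984_at. The other 6 were 1774972_at at 5.26, 1778502_at at 5.08, 1773248_at at 4.37, 1773221_at at 3.64, 1779342_at at 3.60 and 1769739_at at 3.50. The probe set 1773221_at is annotated as rpt3 and 1779342_at as sid2. Neither lower-case symbol is in the S. cerevisiae table, and the sources used here do not give the organism of these probe sets. The S. cerevisiae proteasome ATPase gene RPT3, measured by its own probe set, differed by -0.13 in the same comparison. Of the remaining 3 increases, YJR151W-A (1774893_at), a short open reading frame of 51 bases, was higher by 1.28, and the unnamed 1772598_at and 1769692_at by 1.26 and 1.17.

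The 2 decreases were both S. cerevisiae genes with very short coding sequences. RPL41A, which encodes the small ribosomal protein L41, was at 8.11 in the baseline array, 7.60 in the 1% array and 6.24 in the 10% array, differences of -0.51 and -1.87 from the baseline array. The probe set for RPL41A is of the kind that matches several transcripts, so the near-identical RPL41B may share its signal. The short open reading frame YJL077W-B went from 9.23 to 8.65 and then 7.35, a difference of -1.88 at 10%. Their coding lengths were 78 and 99 bases. In all, 0 probe sets were at least 2-fold lower in both spiked arrays, against 7 that were at least 2-fold higher in both. Both differences use the same baseline array; in 100 simulated sets of unchanged arrays with a spread of 0.077 (log2) per array, the highest number of probe sets higher in both was 0. A difference of 1 lies far outside that spread, so this 0 was fixed by the threshold and does not bear on the 7. Independent lists of 7 and 12 of 10762 would share 0.0078 probe sets, but these lists share the baseline array and are not independent.

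The 10% array was then set against the 1% array, where the stated spike shares have a 10-fold ratio (3.32 on the log2 scale). The 9 responding probe sets fell into 3 with small differences and 6 with larger ones. The 3 bright probe sets differed little between the arrays, by 0.18 for 1773133_at, 0.17 for 1774104_s_at and 0.47 for 1769984_at. In the 10% array, 33 probe sets lay above 1773133_at and 1 above 1774104_s_at, so the differences of these probe sets are at best lower bounds and cannot be set against the 10-fold ratio. The 6 others differed by 2.21 to 3.22, with a median of 2.95; their values in the 1% array, 6.47 to 7.80, can hold background as well, so these too may be lower bounds. The largest of these were 3.22 at 1778502_at and 3.18 at 1774972_at, followed by 3.04 at 1773248_at, 2.87 at rpt3, 2.70 at sid2 and 2.21 at 1769739_at. Their increments over the baseline array on the linear scale were 7.14 to 16.2 times larger in the 10% array than in the 1% array, with a median of 12.7. Over the 7 probe sets higher in both spiked arrays, the median 10% over 1% difference was 2.21 and the quartiles were 0.33 and 3.11. This set is defined by its response, so the values describe it and do not test it. Beyond the 6, 1 further probe set passed 2-fold, YJR151W-A at 1.09, and the same genes as against baseline were at least 2-fold lower, RPL41A with a difference of -1.37 and YJL077W-B with one of -1.30.

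**Figure D2:**
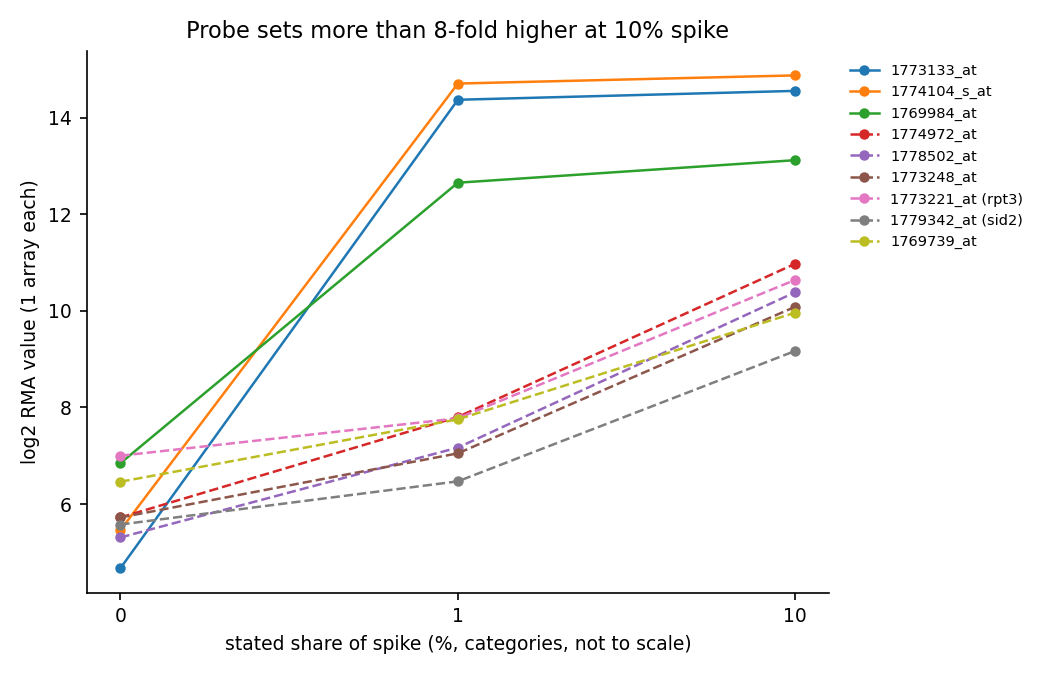
Log2 RMA value (1 array per point) of the 9 probe sets with a 10% over baseline difference above 3, at stated spike shares of 0, 1 and 10%, with the shares drawn as categories. The 3 probe sets with solid lines were already at 12.66 to 14.71 at 1% spike and differed by 0.47 or less from there to 10%, while the 6 with dashed lines differed by 2.21 to 3.22.

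Of the 5498 S. cerevisiae probe sets, 99.6% lay within 0.2 of the baseline value in the 1% array and 95.6% in the 10% array. In the 10% array, 11 of them were higher by 0.3 or more and 85 lower by as much, and at 1.5-fold 2 were higher and 12 lower. The median difference over all non-control probe sets was 0 in each comparison, where dilution alone would give -0.014 (log2 of 0.99) and -0.15 (log2 of 0.90) on an absolute scale; the distributions had been equalized, so a common shift could not show. Over all 10762 probe sets, 98.0% lay within 0.2 of the baseline value in the 1% array and 92.5% in the 10% array. Pearson's r across probe sets, which are not independent replicates, was 0.9988 for 1% against baseline, 0.9979 for 10% against baseline and 0.9993 for 10% against 1%. Without the 7 probe sets higher in both spiked arrays the values were 0.9998, 0.9992 and 0.9995, and the closest pair became 1% against baseline. Spearman's rho was 0.9985, 0.9970 and 0.9983. Many values were exactly equal to 3 decimals, for 63.6% of probe sets between the 1% and the baseline array, for 38.3% between the 10% and the baseline array and for 34.1% in all 3 arrays. In 10 bins of the mean level, the median 10% over baseline difference ran from 0 to 0.007.

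CDC15, the gene carrying the strain's mutation, was at 10.29 in all 3 arrays. ADE2 was at 10.82 and HIS3 at 9.81 in all 3 arrays. URA3 differed by 0.024 between the 10% and the baseline array, CAN1, an arginine permease gene, by 0.026 and LEU2 by 0.11. MATALPHA1, MATALPHA2 and TRP1 were not analysed here, since no probe set carried these names. The alpha-specific genes, which cells of the MAT-alpha mating type express, had a median difference of 0.015 at 10%, with the pheromone genes MF(ALPHA)1 at 14.37 in the baseline array and 14.38 in the 10% array and MF(ALPHA)2 at 14.64 and 14.60. STE3, the a-factor receptor, differed by 0.048, AFB1 by 0.073 and SAG1, the alpha-agglutinin, by 0.014. The genes specific to the opposite mating type had a median difference of 0.023, with ASG7 at 0.095, MFA1 at 0.056, STE6 at 0.039 and AGA2 at 0.023. Their median level in the baseline array was 10.17, against 14.37 for the alpha-specific genes, so they were lower but not at the bottom of the scale.

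Of the 23 gene lists, 22 had measured members, and 4 of the 66 list medians lay apart from level-matched random lists. A call rate of 5% would give 3.3. Exact ties hold many medians at 0, which can hardly be called, so 3.3 may be too high. Simulated unchanged lists were called in 2.5% of 40 cases. They were drawn from all 10762 probe sets for 10% over baseline only, so that rate does not carry over to the 66 medians. The 3 comparisons also share arrays. No list median exceeded 0.028 in size. Cytosolic ribosomal protein genes (127 measured) had a median difference of 0.018 at 10% over baseline, at percentile 99.8 of random lists. Of them, 89 were higher, 20 lower and 18 identical. RPL9A was higher by 0.14, RPL10 by 0.018 and RPL38 by 0.017, whereas RPL4B was at -0.39, RPL15A at -0.17 and RPL41A at -1.87. The list's mean was 0.0014 and lay at percentile 0.26, on the other side of random lists; without RPL41A it lay at percentile 51.4. After quantile normalization over again, the median of all probe sets was -0.014, the list's median -0.005 and its percentile 99.7. In 10% over 1% the median of the ribosomal protein genes was 0.014 (percentile 99.5). After that normalization it was 0, still apart at percentile 98.6, with the median of all probe sets at -0.009. M/G1 genes, expressed as cells leave mitosis (25 measured), had a median of 0.026 in 10% over 1% (percentile 97.9) and of 0.028 in 10% over baseline (percentile 95.4). DSE2, a daughter-cell-specific gene, was higher by 0.22, the cyclin gene PCL9 by 0.21, TEC1 by 0.18 and CLN3 by 0.15 in 10% over baseline. PIR3 was at 0.028 and RME1 at 0.029. The M/G1 percentile in 10% over 1% was 97.0 with the loess trend removed and 96.3 after quantile normalization over again, and either ends the call. Without TEC1 the median was 0.013 (percentile 86.5), which also ends it. Haploid and pheromone response genes had a median of 0.004 in 1% over baseline (percentile 99.9), which was -0.003 at percentile 95.9 after quantile normalization over again (median of all probe sets -0.004) and -0.025 with centred arrays, a setting that moved all probe sets by -0.029. In 10% over baseline their median was 0; PRM3 was at -0.38, PRM2 at -0.16, FIG2 at 0.11, STE12 at 0.10, and STE18 and FUS1 at 0.

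The other lists lay within random lists by their medians. In 10% over baseline, 14 lists had a median of 0. They were ribosome biogenesis, oxidative phosphorylation with the TCA cycle, heat shock chaperones, proteasome, amino acid biosynthesis, iron regulon, phosphate regulon, G1/S genes, core histones, CLB2 cluster, haploid genes, telomeric families, hexose transporters and galactose genes. The median was 0.003 for general stress response genes, 0.0025 for glycolysis, 0.022 for ergosterol biosynthesis and -0.016 for meiosis genes. Members with the largest differences included PHM6 of the phosphate regulon at -0.61, HXT13 of the hexose transporters at -0.61, SPR3 and ZIP1 of the meiosis list at -0.41 and -0.37, and COX9, a subunit of cytochrome c oxidase, at -0.40. On the other side were PAU24 at 0.42, the G1 cyclin gene CLN2 at 0.29, CDA2 and REC8 of the meiosis list at 0.29 and 0.22, CSI2 at 0.28, CRH1 at 0.22 and XBP1, a stress-induced repressor gene, at 0.21. PHM6, HXT13, SPR3 and CDA2 lay at 6.05 to 7.70 in the baseline array, below its median of 7.75. At mean levels of 4.92 to 7.75, 11.6% of 293 S. cerevisiae probe sets were lower by 0.3 or more, and 0.68% were higher by as much. Differences of such dim genes may therefore not be particular to them. Smaller values were found for the ribosome biogenesis genes MAK16 at -0.20 and IMP3 at 0.16, the chaperone gene STI1 at -0.16, the proteasome gene SCL1 at -0.14, the glycolytic gene TPI1 at 0.092, the sterol gene ERG5 at 0.14, the iron permease gene FTR1 at 0.13, ARG4 at -0.14, the histone gene HHF1 at 0.086, TEM1 of the CLB2 cluster at 0.20 and GAL7 at -0.15. Among all list members, 0 were 2-fold higher and 1 was 2-fold lower in 10% over baseline, RPL41A. The list of mitochondrially encoded genes had 0 measured members.

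Control probe sets were read apart. The 42 probe sets for the bacterial poly-A controls dap, lys, phe, thr and trp had a median level of 4.34 in the baseline array and a median 10% over baseline difference of 0. The 17 S. cerevisiae ribosomal RNA probe sets also had a median difference of 0, and the 34 for S. cerevisiae control genes one of 0.011. Control probe sets marked Sp, 22 for genes and 7 for ribosomal RNA, had median differences of 0. Their median levels in the baseline array were 5.09 and 8.03. The 27 probe sets for bioB, bioC, bioD and cre, which are bacterial and phage sequences commonly added as labelled RNA at hybridization, were all higher in the 10% array. Their median difference was 0.51 (1.42-fold), with quartiles of 0.29 and 0.59 and a range from 0.083 to 0.77. In the 1% array their median difference was 0.055, with 22 higher, 5 identical and 0 lower. By sequence, the median at 10% was 0.38 for bioB, 0.63 for bioC, 0.51 for bioD and 0.27 for cre.

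**Figure D3:**
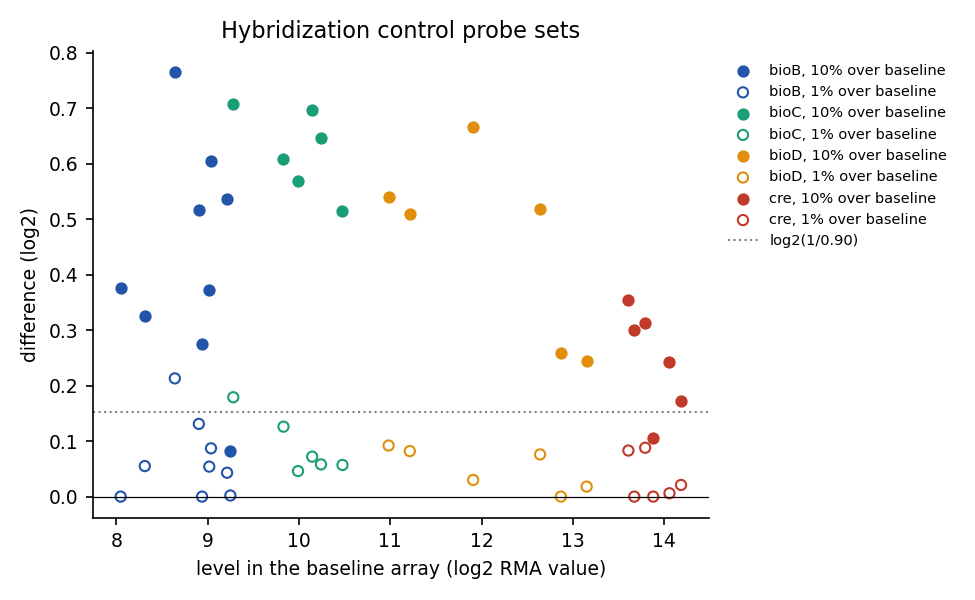
Difference from the baseline array (log2) of the 27 hybridization control probe sets against their level in the baseline array, for 10% spike (filled) and 1% spike (open); the dotted line is log2(1/0.90), 0.15. All 27 filled points lie above 0, and the cre probe sets, at 13.61 to 14.18, have a median of 0.27.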

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

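All tests in this part were chosen after the results they bear on were seen, and no biological explanation was tested, since every array holds the same yeast background. The hybridization controls, which lie outside the counts of changed probe sets, differed between the arrays: their median 10% over baseline difference was 0.51 (log2), with 27 of 27 probe sets higher. Dilution of the yeast RNA to 90% would raise a fixed amount of control by 0.15 relative to the background. The lower quartile of the controls was 0.288, above that value. The 27 probe sets share the sequences bioB, bioC, bioD and cre on 1 array, so their quartile does not measure how much arrays vary. Dilution by that share alone therefore cannot be excluded. A shift that normalization gave to every probe set of that level could not be judged. Of 10000 level-matched lists of S. cerevisiae genes, 0 reached the controls' median, and the highest list median was 0.075. Equalized distributions hold such lists near 0 in any case, so this result does not decide the question. Less labelled yeast RNA or more control mixture on the 10% array stays open and was not tested.

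The 3 brightest responding probe sets differed by 0.17 to 0.47 between 1% and 10% spike, where the stated shares differ by 3.32. Nearly equal spike amounts on both arrays cannot be judged for these 3. Over the 7 probe sets at least 2-fold higher at 1% spike, these 3 included, the ratio of linear increments (10% to 1%) had a median of 7.14. It was above 2 in 4 of them, which goes against nearly equal amounts of what those 4 measure. Their 10% over 1% differences had been seen before, so this result was known in advance. Whether the 4 respond to the same spiked RNA as the 3 bright probe sets, whose ratios were 1.12 to 1.39, is not known. The top of the normalized scale is argued against for 1769984_at, with 516 probe sets above it in the 10% array; for 1773133_at and 1774104_s_at it cannot be told apart from other causes, with 33 probe sets above the lower of them and 1 above the higher. Compression at high signal may contribute: from 1% to 10%, 7 hybridization controls above 13 differed by a median of 0.23 and 16 under 11 by 0.47, a gap of 0.24 (0.2425). The controls at each level are mostly different transcripts, with only bioD in both groups. Their change did not simply fall with level, since the median was 0.375 for bioB, the dimmest, and 0.53 for bioC. The controls' own change is also too small to show how far compression reaches in the 3 probe sets, which stays open.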

How the results depend on the processing

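List means, lists without 1 member, and the list and length values without RPL41A and YJL077W-B were chosen after the data were seen; the other alternatives were planned. All 14 probe sets past 2-fold in 10% over baseline kept their direction under centring, quantile normalization over again and loess. These settings moved the median of all probe sets by at most 0.047 in any comparison. The smallest of the 14 differences was 1.17 in size, so the kept directions show little. Counts and correlations stayed within the stated limits with dim probe sets left out. They also did, as far as each applies, with control probe sets kept or without the probe sets higher in both spiked arrays. The last setting cannot move the lists, since those probe sets are unnamed, but it turned the order of Pearson's r, so that 1% against baseline became the closest pair. The first 2 settings could not change the 2-fold counts. All 14 probe sets past 2-fold were above the lower quartile, and control differences ran only from -0.509 to 0.765. With a threshold of 1.5-fold, 30 probe sets were higher and 14 lower in 10% over baseline, 19 higher and 7 lower in 10% over 1%, and the set higher in both spiked arrays had a median 10% over 1% difference of 2.70. With a threshold of 4-fold, 4 were higher in 1% over baseline, 0 lower in 10% over baseline and 0 lower in 10% over 1%; 4 were higher in both spiked arrays, with a median of 0.33 (0.3255), as this keeps the 3 bright probe sets and 1774972_at. With probe sets averaged per named gene, 0 were higher in 1% over baseline, 3 in 10% over baseline, 3 in 10% over 1% and 0 in both spiked arrays, since unnamed probe sets drop out and leave no set for a median. The number of gene lists apart from random lists in 10% over baseline went from 1 to 2 after quantile normalization over again (heat shock chaperones at percentile 2.08 joined the ribosomal proteins) and to 2 with unmatched random lists, and in 10% over 1% from 2 to 1 after loess; the cause was not tested. Quantile normalization over again also exchanged lists elsewhere: in 1% over baseline the haploid genes dropped out and ribosomal proteins came apart on the low side (percentile 2.2), and in 10% over 1% M/G1 genes dropped out while ribosome biogenesis (0.765) and proteasome (0.86) came apart, giving 3. With list means it was 2 in 1% over baseline and 3 in 10% over baseline. Without the member of largest absolute difference, no list stayed apart by its mean (M/G1 genes missed the limit narrowly in 10% over baseline, at percentile 97.0), and by medians M/G1 genes dropped out in 10% over 1% (percentile 86.5) while the ribosomal protein and haploid genes stayed. The pseudocount planned for linear values was not run, since the values are on a log scale. No paired analysis was possible because each group has 1 array, so no replicate could be left out either. Dim probe sets lie near background, and exact ties limit what a median of 0 shows.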

Other observations

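The list means, the lists without 1 member, the gap without RPL41A and YJL077W-B and the comparison of classes by level were chosen after the data were seen. Both S. cerevisiae genes that were at least 2-fold lower at 10% spike have very short coding sequences. The only one at least 2-fold higher, YJR151W-A, is shorter still, at 51 bases. The 2 falls led to a look at gene length over 5446 protein-coding genes, with introns counted where a gene has them. The shortest 545 genes (51 to 453 bases) had a mean 10% over baseline difference of -0.032 against 0.0082 for the others, and in the bins of longer genes the means lay between 0.00075 and 0.013. Of the shortest genes, 23 were lower by 0.3 or more and 5 higher by as much. In each bin of longer genes, 3 to 10 were lower by that much and 0 to 2 higher. Short genes thus spread more in both directions. In 1% over baseline the mean of the shortest genes was -0.0023, at percentile 33.6 of level-matched lists.

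A loss tied to gene length may contribute to this pattern. The test was fixed before its result, but the pattern was noticed from the top falls of the same data. The gap in means was -0.041 (log2). The mean of the shortest genes lay at percentile 0.02 of level-matched random lists, whose 95% range was -0.025 to -0.0070. These lists are themselves below the other genes, so part of the gap goes with level. The 2 strongly lower genes alone are argued against, since the gap was -0.034 without them. The gap in medians was 0, which exact ties nearly fix, so it shows little either way. With 1 array per condition, a preparation difference of the 10% array cannot be separated from an effect of the spike.

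By list means, oxidative phosphorylation and TCA cycle genes were at -0.0061 in 10% over baseline (percentile 0.48), with 19 higher and 15 lower, and M/G1 genes were at 0.049 (percentile 99.3). The iron regulon was at 0.015 in 1% over baseline (percentile 97.8). Each of these calls ended without the list's most extreme member. Without COX9, which has a coding length of 180 bases, the first mean changed sign, to 0.0032 (percentile 4.91). Without DSE2 the M/G1 mean was nearly as large, at 0.042 (percentile 97.0), and missed the limit narrowly. Without SIT1 the iron regulon mean was 0.011 (percentile 92.3). Of the 47 reporter probe sets, none was 1.5-fold higher or lower in the 10% array, with a range from -0.41 to 0.38.

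At 10% spike, increases of 0.3 or more, those past 2-fold included, were found mostly outside S. cerevisiae genes: 137 of 3470 unnamed probe sets (3.95%), 39 of 1747 with other symbols (2.23%) and 11 of 5498 S. cerevisiae probe sets (0.20%) were higher. Decreases of 0.3 or more were found for 42 unnamed probe sets (1.21%), 26 with other symbols (1.49%) and 85 S. cerevisiae probe sets (1.55%). The classes differ in level, with median levels of 4.95, 4.86 and 10.82. At levels from 4.92 to 7.75, and without the probe sets past 2-fold, 291 S. cerevisiae probe sets had a mean 10% over baseline difference of -0.11 and 2386 others one of 0.022. With all kept, 11.6% of 293 S. cerevisiae probe sets were lower by 0.3 or more, against 1.88% of 2391 others. Below that range the means were -0.079 for 51 S. cerevisiae probe sets and 0.016 for 2646 others. Above it, where most S. cerevisiae probe sets lie, they were close: 0.0020 against 0.0077 at levels up to 10.92, and 0.021 against 0.027 beyond, again without the probe sets past 2-fold.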
